A study of Mus musculus with 24 samples.

How the data were processed

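The series measured messenger RNA in brain, heart and liver of 5-week-old female C57BL/6 mice. An aqueous extract of Ephedra herba, the dried stems of a plant used in traditional medicine, was given by mouth at 50 mg/kg per the labels. Tissue was taken 1 hour, 6 hours, 12 hours, 24 hours, 3 days, 5 days and 10 days after dosing began, and from untreated mice. The labels name 24 arrays, 1 for each tissue and time, so no tissue and time has a replicate. Whether the dose was repeated, whether the 3 tissues of a time came from the same animals, how many animals were pooled and at what clock time tissue was taken are not given in the sources used here. Per the labels, total RNA was amplified to biotinylated cRNA for Illumina bead arrays.

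The deposited table of 25697 probes by 24 arrays holds log2 values, with the base taken as 2 because no label states it. The authors' background correction, normalization and software are not given in the sources used here. The values themselves show that each array was centred near 0 and that spread was equalised within a tissue. Array medians ran from -0.016 to 0.0026. The median absolute deviation was 0.803 to 0.809 in brain, 0.596 to 0.600 in heart and 0.356 to 0.367 in liver. A second deposited table of intensities was not used here, because its 24 value columns match no sample label and columns were not assigned by their order or values. Without it no detection p-values, bead counts or background levels were available, and a probe was counted as detected on an array where it lay above that array's median.

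Of the probes, 23141 had 1 gene symbol and 2556 had none, which left 16110 genes. A gene was taken by its probe with the highest mean, a choice that applied to 4507 genes with over 1 probe. Tests covered the 10934 genes above the median on at least 4 of the 24 arrays. This limit is lenient: Uty, a Y-linked gene, lay above the median on 8 of 8 brain, 8 of 8 heart and 5 of 8 liver arrays of these female mice. The Y-linked genes Eif2s3y and Kdm5d lay above it on 0 arrays. The highest Pearson correlation between 2 arrays across probes was 0.996, so no array was a copy of another. Chromosome positions were not used here.

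The comparisons, tests, gene lists and the rule for naming genes were written down before the data were examined. Linear models were fitted to all tested genes with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a call at an adjusted p under 0.05. Tissue contrasts used time as a block. Treated against untreated, each time against untreated, the slope on log2 hours, and 6 and 12 hours against the whole days (24 hours, 3, 5 and 10 days) used tissue as a block. Treated against untreated was also tested in each tissue, as was 6 and 12 hours against the whole days, each time with 1 spread shared by all groups and an F test of the difference between tissues. In a single tissue the lone untreated array was assumed to vary like the treated arrays. Changes at 1 time in 1 tissue rest on 1 array against 1 and have no test; genes at least 2-fold changed and detected on the brighter array were counted.

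The 56 gene lists hold 754 genes, of which 644 are on the array. The 50 lists with at least 4 tested members were tested in 16 contrasts with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a contrast. Measured members of a list in a contrast are these tested members. Mean levels of a list can include further members that are on the array but were not tested. For single arrays a list's median change was set against 10000 random lists of the same size and expression. Genes were named by rule. For a tested contrast these were the up to 10 largest rises and 10 largest falls among called genes at least 1.5-fold changed, with 1 sign in all 3 tissues for contrasts across tissues. For single arrays they were the up to 4 largest changes each way, and the up to 8 each way among genes with 1 direction at all 7 times. Of a list, up to 4 members were named.

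The plan called for no further normalization if the table proved to be normalized already. All fits were nevertheless first run on values quantile-normalized over the 24 arrays. They were then rerun on the deposited values as they stand, after the results of the first run had been seen. The values reported are those of the rerun, and the first scaling is kept as an alternative chosen after seeing the data. The alternatives chosen beforehand were quantile normalization within each tissue, a shift of each array to 1 median, no detection filter, detection on all 8 arrays of a tissue, the mean of a gene's probes, a variance trend with robust eBayes, leaving out each tissue or time, the rank of time, a 1.5-fold threshold, detection on both arrays, and the mean of the other 7 arrays as reference. An array set as a block, fits within a set, the atrial and hepatocyte lists without heart, the ribosomal list in brain without 12 hours, the interferon list in heart at 6 and 12 hours each, and each time without the 12 hour brain array were added after seeing the data. So was a simulation of unchanged arrays, drawn from a normal distribution, that share 1 reference array. Calls between sets of arrays were computed once and not used, because the sets were defined from the values. The tests were tried on simulated data with 10934 genes of which 100 were changed 2-fold and 100 were changed 4-fold. For 12 hours against untreated they recovered 73% and 93% of these, for treated against untreated across tissues 86% and 100%, and for treated against untreated in heart 55% and 93%. False calls numbered 11 of 177 calls for 12 hours and 13 of 199 for treated against untreated across tissues. The simulated noise was the spread left after fitting tissue and time, so it held no differences between times or array sets. The fits of treated against untreated keep such differences in their spread, so real recovery may be lower and few calls do not show that few genes changed. The number of arrays limits the precision of every value.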

Results

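Expression was measured on 24 bead arrays, 8 from brain, 8 from heart and 8 from liver, with 1 array for untreated mice and 1 for each of 7 times after an oral Ephedra herba extract. The values are the deposited log2 intensities, centred near 0 on each array. There are no replicates of any tissue at any time, so tests across tissues used the 3 tissues as replicates of a time (n = 3 arrays per time). The p-values measure only the spread between these samples. Arrays differed in shape within a tissue: the highest value was 8.29 on the untreated liver array and 10.8, 10.6 and 11.2 on the liver arrays of 6, 12 and 24 hours. Across probes, which are not independent replicates, the arrays were put into sets by the lower tail of their values, a grouping made after the values were seen. The untreated, 1 hour and 10 day arrays formed 1 set, those of 6, 12 and 24 hours and 5 days another, and those of 3 days were kept apart, although the 5th percentile of the 3 day heart array, -0.714, lay within the range of the second set (-0.721 to -0.714). The median Spearman correlation within and between sets was 0.978 and 0.963 in brain, 0.971 and 0.948 in heart, and 0.913 and 0.853 in liver. The 5 day liver array was an exception, at a median of 0.830 with its own set. The untreated arrays lie in a single set, so the set and the time cannot be told apart at 6, 12 and 24 hours, 3 days and 5 days.

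The myelin gene Mbp averaged 8.31 ± 0.17 (SD, n = 8) in brain, 0.90 ± 0.60 in heart and -0.14 ± 0.10 in liver. The heart muscle genes Myh6 and Nppa averaged 8.68 ± 0.49 and 8.65 ± 0.37 in heart, against -0.17 ± 0.37 and 0.31 ± 0.76 in brain. Apoa1, the main protein of high-density lipoprotein, and Cps1, the first enzyme of the urea cycle, averaged 9.18 ± 1.33 and 7.99 ± 1.24 in liver (SD, n = 8). In heart they averaged 1.96 ± 1.99 and 0.16 ± 0.97, and in brain 0.45 ± 0.65 and -0.61 ± 0.15. The albumin gene Alb averaged only 1.67 ± 0.56 in liver, against -0.66 in heart and -0.91 in brain. By list, neuron genes averaged 3.71 ± 0.08 in brain, cardiomyocyte genes 7.16 ± 0.34 in heart and hepatocyte genes 7.04 ± 0.90 in liver. Xist, expressed from the inactive X chromosome of females, averaged 2.25 ± 0.28, 0.94 ± 0.50 and 1.60 ± 0.56 in brain, heart and liver. The probe of the neuronal gene Snap25 lay below the median on all 8 brain arrays, at -0.68 ± 0.12, and averaged -0.52 in heart and -0.35 in liver. Slc1a2, on the lists of astrocytes and of liver cells near the central vein, averaged 3.99 ± 0.21 in brain and 5.06 ± 1.01 in liver, and Ttr, on those of choroid plexus and hepatocytes, 7.60 ± 0.41 and 8.89 ± 1.10. Of 10934 genes, 3754 were higher and 4051 lower in heart than in brain, 3350 higher and 4986 lower in liver than in brain, and 2699 higher and 4444 lower in liver than in heart. Without the detection filter the totals rose from 7805, 8336 and 7143 to 11914, 13176 and 11173.

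Treated against untreated arrays were compared in the mean over the 3 tissues and all times, which a single tissue can carry. By limma 0 of 10934 genes passed (21 against 3 arrays, lowest adjusted p = 0.286), with 1215 at an unadjusted p under 0.05. Among fixed lists, the 10 measured clock genes that peak with Dbp had a mean log2 change of 0.62 (camera adjusted p = 0.0053), with Ciart at 1.56 and Per2 at 1.32. Glucocorticoid-responsive genes averaged 0.34 over 14 members (adjusted p = 0.0082), with Lcn2 at 0.98 and Fkbp5 at 0.75. As deposited, liver carried this (0.96, against 0.06 in brain and 0.01 in heart), a split that depends on the scaling. White fat genes averaged -0.70 over 5 members (adjusted p = 0.0342), with Adipoq at -1.06 and Cidec at -0.87, and heart carried this (-2.41, against -0.08 in brain and 0.38 in liver). With an estimated correlation each of these 3 lists had an adjusted p = 0.856. Adjusted over the list alone, 0 members of the first pair of lists passed, and 3 of 5 white fat genes fell. Cerebellar genes averaged 0.65 (adjusted p = 0.011; 1.85 in brain, 0.04 in heart and 0.06 in liver) and endothelial genes -0.27 (adjusted p = 0.011; 4 of 11 lower adjusted over the list alone). Both had an adjusted p = 0.856 with an estimated correlation, and the endothelial call ended with quantile normalization within tissues (adjusted p = 0.110). Xenobiotic metabolism genes averaged 0.10 over 24 members, with 0.57 in liver, -0.25 in heart and -0.02 in brain (adjusted p = 0.0462, and 0.856 with an estimated correlation), a call that also ended with quantile normalization within tissues (adjusted p = 0.462). Over all contrasts, camera with the preset correlation made 87 list calls, and 2 of them held with an estimated correlation.

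In heart, genes of fat cells fell. Car3, a carbonic anhydrase abundant in fat, fell by 4.36 on the log2 scale (SE 0.84, adjusted p = 0.0378). Adipoq, which encodes the fat hormone adiponectin, fell by 3.35 (SE 0.37, adjusted p = 3.68e-05). Cidec, a lipid droplet protein, fell by 2.98 (SE 0.27, adjusted p = 1.21e-06), a size that is not exact because its treated mean of -0.06 lay near the array median, and Adig, which encodes adipogenin, fell by 2.33 (SE 0.19, adjusted p = 5.67e-07). Each of these 4 genes was lower on all 7 treated heart arrays than on the single untreated one, as were 27.7% of heart genes. In simulated unchanged arrays that share 1 reference the share was 12.7%. With each other heart array as the reference it ran from 4.48% to 21.05%. The 95th percentile was 4.89 on the untreated heart array and 4.36 to 4.84 on the treated ones. Such a difference in scale can put bright genes lower on the treated arrays, so the share alone does not show a change. The share is given for the deposited values only. In all 12 genes fell and 0 rose (limma, 7 arrays against 1), and 7 passed with detection on all 8 arrays of a tissue. Also named were the desaturase Scd1 (-2.81, SE 0.45), the neutrophil protein gene S100a8 (-2.29, SE 0.41), Tnfrsf12a (-1.99), the glutamate transporter gene Slc1a3 (-1.76), the citrate carrier gene Slc25a1 (-1.67) and Car5b (-1.12). The median over all genes was -0.12 here and -0.02 with quantile normalization within tissues; relative to the median gene, Car3 changed by -4.24, Adipoq by -3.23, Cidec by -2.86 and Adig by -2.21. Scd1, Tnfrsf12a and Slc25a1 lost their calls with that normalization (adjusted p = 0.396, 0.0542 and 0.0689).

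**Figure D1:**
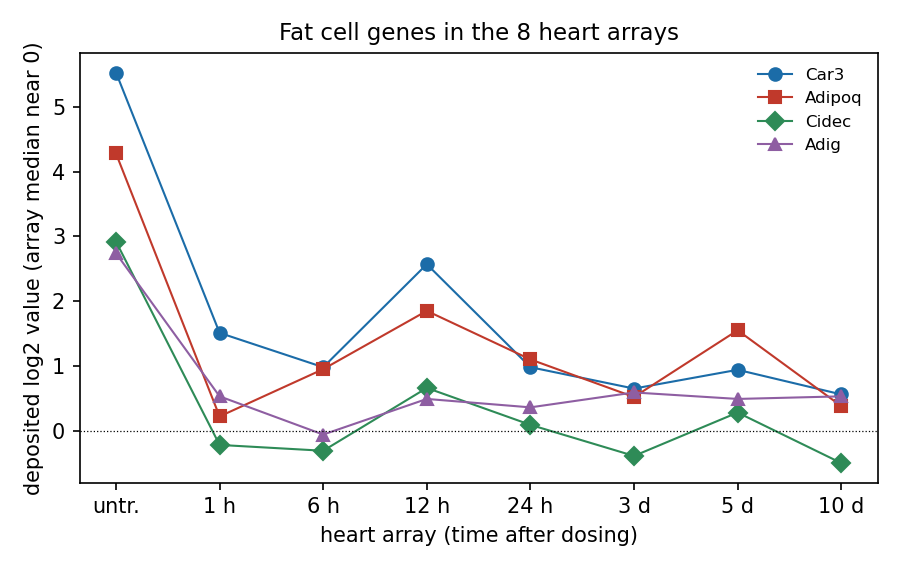
Deposited log2 values (vertical axis, array median near 0) of 4 fat cell genes on the 8 heart arrays, untreated and by time after dosing (horizontal axis), 1 point per array. All 4 genes were highest on the untreated array, Car3 at 5.53 and Adipoq at 4.28, while the treated arrays ranged from 0.56 to 2.57 for Car3 and from 0.22 to 1.85 for Adipoq.

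The white fat list averaged -2.41 over 5 measured members in heart (adjusted p = 6.62e-16, and 3.36e-04 with an estimated correlation). Of its members 3 fell over all genes tested and 5 fell adjusted over the list alone. The white fat list moved by -2.42 at 1 hour already and by -2.74 at 10 days. Cardiac stress genes averaged -1.18 over 7 members (adjusted p = 2.18e-04, and 0.299 with an estimated correlation), with Nppb at -2.04 and Ankrd1 at -1.20; 2 of 7 fell adjusted over the list alone. The cardiac stress list's median at 6, 12 and 24 hours and 5 days was -1.52, -1.49, -1.65 and -1.48 as deposited and -0.75, -0.49, -0.49 and -0.46 with quantile normalization over all 24 arrays, and that of cardiomyocyte genes at 6 hours -1.05 and -0.19. Clock genes of the Dbp phase averaged 0.93 in heart (adjusted p = 2.18e-04, and 0.357 with an estimated correlation), neutrophil genes -0.76 (adjusted p = 0.0097, and 0.357 with an estimated correlation). Endothelial genes averaged -0.48 (adjusted p = 3.82e-04, and 0.357 with an estimated correlation). Extracellular matrix genes averaged -0.43 (adjusted p = 0.009, and 0.709 with an estimated correlation) and atrial genes -1.06 (adjusted p = 0.0475, and 0.709 with an estimated correlation). The endothelial, matrix and atrial calls ended with quantile normalization within tissues (adjusted p = 0.0907, 0.206 and 0.256). The change differed between tissues in 3 genes, Adig (adjusted p = 6.73e-05), Cidec (8.59e-05) and Adipoq (0.0036), with 104 at an unadjusted p under 0.05.

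In brain, cerebellar genes were higher and hypothalamic genes lower in the mean over the 7 times than on the untreated array, but at 1 hour the cerebellum list was at -0.34. The Purkinje cell gene Pcp2 changed by 3.41, En2 by 2.29, Zic1 by 1.70 and Cbln1 by 1.58. The list averaged 1.85 (adjusted p = 1.25e-06, and 0.771 with an estimated correlation), and 4 of 5 members rose adjusted over the list alone. The neuropeptide genes Avp, Cartpt, Oxt and Hcrt changed by -1.38, -1.24, -1.15 and -0.92. The hypothalamus list averaged -0.79 (adjusted p = 1.14e-04, and 0.771 with an estimated correlation), and 4 of 7 members fell adjusted over the list alone. Over all genes tested 0 passed in brain by limma (lowest adjusted p = 0.915), with 427 at an unadjusted p under 0.05.

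In liver, 0 genes passed by limma, with 224 at an unadjusted p under 0.05. The lowest adjusted p, 0.0731, belonged to the chemokine gene Cxcl1, at -2.57. With a variance trend and robust eBayes, 1 gene passed. Glucocorticoid-responsive genes averaged 0.96 over 14 members (adjusted p = 3.12e-06), with Lcn2 at 2.55 and Dusp1 at 1.92. Xenobiotic metabolism genes averaged 0.57 over 24 members (adjusted p = 2.53e-06), with Cyp2b10 at 1.49 and Cyp2a5 at 1.19. The list's median at 6, 12 and 24 hours was 0.90, 1.12 and 1.28 as deposited and -0.03, 0.22 and 0.28 with quantile normalization over all 24 arrays, where the call held. Interferon-stimulated genes averaged -0.22 (adjusted p = 0.0033), cytokine and NF-kB target genes -0.36 (adjusted p = 0.0151) and cell cycle genes 0.30 (adjusted p = 0.0029). Each of these lists had an adjusted p = 0.655 with an estimated correlation. Adjusted over the list alone, 1 of the 9 cytokine genes fell and 0 members of the other 4 lists passed. The cytokine call ended with quantile normalization over all 24 arrays (adjusted p = 0.0723). Oxidative phosphorylation genes averaged 0.53 (adjusted p = 1.91e-05) and ribosomal protein genes 0.49 (adjusted p = 0.0021), both at 0.655 with an estimated correlation; with quantile normalization within tissues they averaged 0.15 and 0.02 and their calls ended (adjusted p = 0.154 and 0.619).

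Each time against untreated across tissues addressed the time course named in the series title. Atp5a1, the alpha subunit of ATP synthase, rose by 2.01, 1.74, 1.99, 1.94 and 1.94 at 6, 12 and 24 hours, 3 days and 5 days (log2, SE 0.27, 3 arrays against 3, highest adjusted p = 0.0058). Aldh6a1, an enzyme of valine breakdown, rose by 1.77, 1.60, 1.88, 1.46 and 1.79 (SE 0.21). Idh2, the mitochondrial isocitrate dehydrogenase, rose by 1.65 at 6 hours, 1.61 at 24 hours, 1.46 at 3 days and 1.65 at 5 days (SE 0.17). Nampt, an enzyme of NAD synthesis, rose by 1.52, 1.54 and 1.51 at 6, 12 and 24 hours (SE 0.26). Ndufb5, a complex I subunit, rose by 1.46 at 6 hours, 1.34 at 3 days and 1.52 at 5 days (SE 0.25). Among others named, Chp1 rose by 1.64, 1.62 and 1.77 at 6 and 12 hours and 5 days. 4833439L19Rik rose by 1.48, 1.48 and 1.45 at 6, 12 and 24 hours. Sptssa rose by 1.39 to 1.52 at 6 and 24 hours, 3 days and 5 days. By the rule for naming, these genes had the same sign in all 3 tissues. At 12 hours other probes moved less for Chp1 (0.30 and 0.54) and 4833439L19Rik (0.19 and 0.06), all above the median on 24 arrays. Other probes moved nearly as far as the chosen one for Ciart (2.017 against 2.205) and Nr1d1 (-1.29 against -1.40).

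Junb, an immediate early transcription factor gene, fell by 1.49, 1.82, 1.63 and 1.30 at 6, 12 and 24 hours and 5 days (log2, SE 0.22). Spon2, a secreted matrix protein gene, fell by 1.88, 1.75, 2.21 and 1.78 at the same times (SE 0.45). Hspb1, a small heat shock protein gene, fell by 1.32 and 1.57 at 6 and 12 hours (SE 0.30), and Cryab, another, fell by 1.35 and 1.15 at 12 and 24 hours (SE 0.29). Fscn1, which bundles actin, fell by 1.21, 1.25, 1.23 and 1.03 (SE 0.22). The calls of Hspb1 at 6 hours and Cryab at 24 hours ended with quantile normalization within tissues (adjusted p = 0.0524 and 0.123). That check is not given here for Hspb1 at 24 hours. At 5 days the beta-globin gene Hbb-bt rose by 1.71 (SE 0.41, adjusted p = 0.0416) and the red cell membrane gene Slc4a1 by 1.42 (SE 0.31, adjusted p = 0.0283), while the basement membrane collagen gene Col4a1 fell by 1.28 (SE 0.31, adjusted p = 0.0415). At 3 days Pabpc1, a poly(A)-binding protein gene, rose by 1.52 (SE 0.25) and Gpd1, a glycerol phosphate dehydrogenase gene, fell by 1.04 (SE 0.16).

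By limma, 118 genes rose and 246 fell at 6 hours, 144 and 443 at 12 hours, 85 and 210 at 24 hours, 26 and 9 at 3 days, and 79 and 137 at 5 days. At 1 hour and 10 days 0 genes passed, with 95 and 126 at an unadjusted p under 0.05. Both numbers are below a share of 0.05 of the 10934 genes, so these tests were conservative. The spread was shared by all times, and 0 calls do not show that 1 hour and 10 days were unchanged. Over all times 471 genes differed (F test). The split between rises and falls moved with the scaling: quantile normalization within tissues gave 234 and 239, 374 and 464, 189 and 152, 51 and 6, and 153 and 99 at the same 5 times. Without heart 0 genes passed at any of the 5 times, and without brain 3, 1, 6, 1 and 2, while without liver 1487, 2710, 1635, 172 and 1374 passed. Leaving out the 12 hour brain array alone, chosen after seeing the data, changed the total at 12 hours from 587 to 156 and those at 6 and 24 hours, 3 days and 5 days to 510, 414, 88 and 310.

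**Figure D2:**
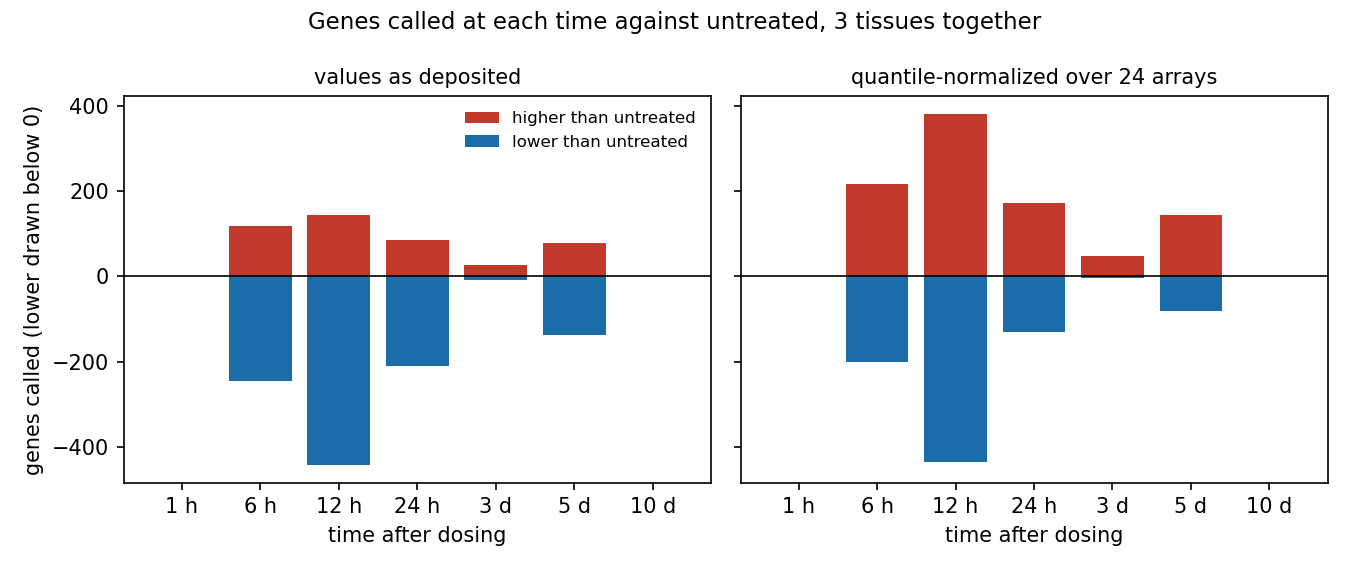
Number of genes (vertical axis) higher than untreated (bars above 0) or lower (bars below 0) across the 3 tissues at an adjusted p under 0.05, by time after dosing (horizontal axis), with the values as deposited (left) and quantile-normalized over all 24 arrays (right). The 12 hour comparison had 144 higher and 443 lower as deposited and 381 and 435 quantile-normalized, but 28 and 128 as deposited without the 12 hour brain array, and those of 1 hour and 10 days had 0 in both.

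Clock genes made up the list most often called among these times. The list of 10 genes that peak with Dbp averaged 0.83 at 6 hours, 0.86 at 12 hours, 1.03 at 24 hours, 0.68 at 3 days and 0.96 at 5 days. The camera adjusted p was 0.0084, 0.0077, 0.0012, 3.13e-04 and 6.57e-04, and with an estimated correlation the adjusted p was 0.946, 0.931, 0.878, 0.945 and 0.992. At 24 hours Ciart, a clock repressor gene, rose by 2.71 (SE 0.71, adjusted p = 0.0494) and Dbp, an output transcription factor gene, by 2.24 (SE 0.58, adjusted p = 0.0472). Per3 rose by 1.37 at 12 hours (SE 0.26, adjusted p = 0.01). Nr1d1, the repressor REV-ERB alpha and a member of the same list, went the other way and fell by 1.43, 1.40, 1.29 and 1.07 at 6, 12 and 24 hours and 5 days (SE 0.23). The 5 day call ended with quantile normalization within tissues (adjusted p = 0.0604). Adjusted over the list alone, 6 members rose and 1 fell at 6, 12 and 24 hours, 2 rose at 3 days, and 7 rose and 1 fell at 5 days. Single-array changes of Dbp at 24 hours were 0.98 in brain, 2.43 in heart and 3.32 in liver as deposited, and 1.28, 3.08 and 1.96 with quantile normalization over all 24 arrays.

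**Figure D3:**
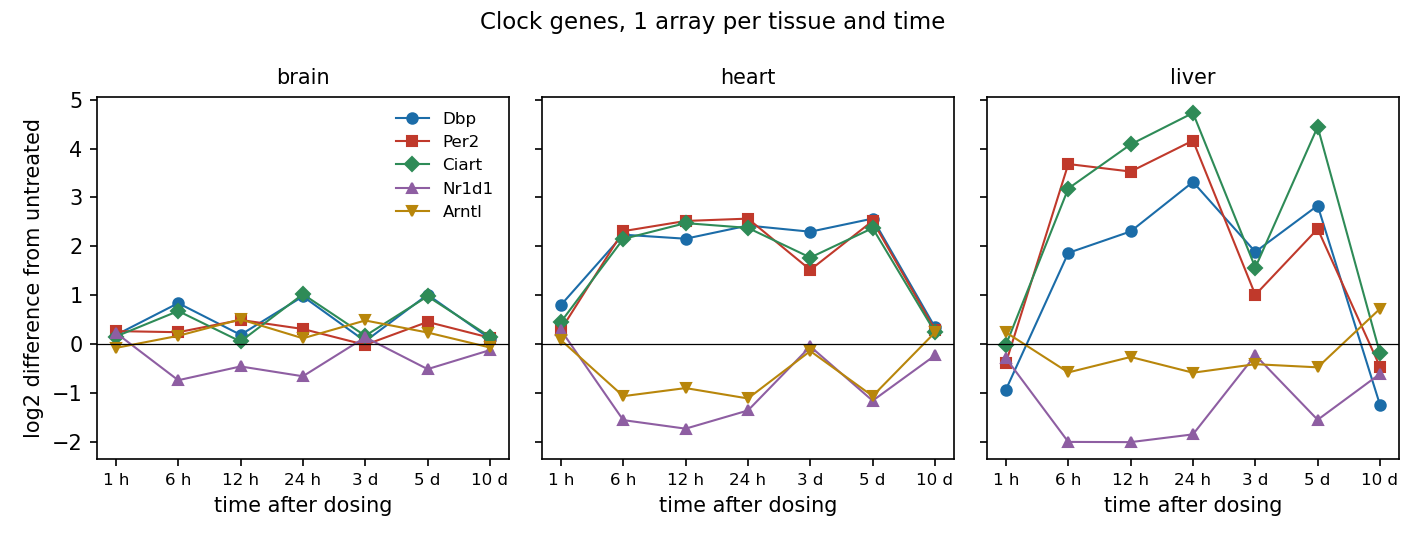
Log2 change from the untreated array of the same tissue (vertical axis) for clock genes at each time after dosing (horizontal axis), 1 point per array in brain, heart and liver. Ciart in liver was at 3.18, 4.09 and 4.73 at 6, 12 and 24 hours and at -0.02 and -0.19 at 1 hour and 10 days, while Nr1d1 in liver was at -2.00, -2.01 and -1.85 at 6, 12 and 24 hours; the small changes of Per2 in brain and Nr1d1 in heart at 3 days change sign with quantile normalization.

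Glucocorticoid-responsive genes averaged 0.60 at 6 hours, 0.60 at 12 hours, 0.69 at 24 hours and 0.41 at 5 days (adjusted p = 0.0082, 0.0055, 0.001 and 0.0076). With an estimated correlation the adjusted p was 0.946, 0.931, 0.878 and 0.992. As deposited, liver carried these means, at 1.57, 1.78, 1.98 and 1.04, while brain ranged from -0.03 to 0.29 and heart from -0.11 to 0.11. The split depends on the scaling. With quantile normalization over all 24 arrays the list's brain median at 12 hours went from -0.18 to 0.31, and its liver medians fell (Other observations). At 1 hour the list averaged 0.27, with 0.22 in brain, 0.42 in heart and 0.18 in liver. At 12 hours Fkbp5, a co-chaperone of the receptor, rose by 1.35 (SE 0.38, adjusted p = 0.0493), as did Sgk1 by 1.19 (adjusted p = 0.0496) and Tsc22d3 by 1.04 (adjusted p = 0.0295). These 3 of 14 members rose both over all genes and adjusted over the list alone. Cell cycle genes averaged 0.36 at 6 hours and 0.23 at 12 hours (adjusted p = 7.92e-05 and 0.0077, and 0.946 and 0.931 with an estimated correlation), with 3 and 1 of 19 higher adjusted over the list alone and means of 0.90 and 0.71 in liver, 0.02 and -0.04 in brain and 0.16 and 0.03 in heart. Endothelial genes averaged -0.41 at 5 days (adjusted p = 0.0076, and 0.992 with an estimated correlation), with Cdh5, the endothelial cadherin, lower by -0.90 (adjusted p = 0.0192) and 5 of 11 lower adjusted over the list alone. Oxidative phosphorylation genes averaged 0.31 at 6 hours, 0.31 at 24 hours and 0.10 at 5 days, where the median was -0.19 (adjusted p = 0.0082, 0.0055 and 0.0485). With an estimated correlation the adjusted p was 0.946, 0.878 and 0.992; 4, 4 and 6 of 28 were higher adjusted over the list alone. As deposited, heart went the other way, at -0.25, -0.40 and -0.28, against 1.12, 1.24 and 0.30 in liver and 0.05, 0.10 and 0.27 in brain. These tissue means are given for the deposited values only. Both this list at these times and the endothelial list at 5 days lost their calls with quantile normalization within tissues.

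At 1 hour, genes of the exocrine pancreas averaged 1.37 (adjusted p = 1.39e-16) and of skeletal muscle 0.86 (adjusted p = 3.04e-11) across tissues, both at 0.135 with an estimated correlation. From untreated to 1 hour the skeletal muscle genes went from an average of -0.06 to 2.43 in liver, 0.33 to 0.38 in brain and 1.69 to 1.59 in heart. Cela2a, a pancreatic elastase gene, was at 1.83 and Acta1, skeletal actin, at 1.82; 0 members of either list passed adjusted over the list alone. The exocrine pancreas genes averaged 4.13 on the 1 hour liver array, where 16 of 16 lay above the median, and 0.05 to 0.18 on the other 7 liver arrays. Atrial genes averaged -0.70 at 1 hour (adjusted p = 2.85e-05, and 0.156 with an estimated correlation), with Myl7 at -1.09 and Myl4 at -1.08. The heart array carried this, at -2.06 against -0.43 in brain and 0.40 in liver, and without heart the mean was -0.01. At 10 days cytokine and NF-kB target genes averaged -0.33 over 9 members (adjusted p = 1.13e-04, and 0.0437 with an estimated correlation), with Socs3 at -0.91 and Cxcl1 at -0.81. Adjusted over the list alone 1 of 9 fell. The fall was largest in liver, at -0.64 against -0.10 in brain and -0.26 in heart, and Cxcl1 was at -2.71 in liver. Immediate early genes averaged -0.30 over 17 members at 10 days (adjusted p = 1.13e-04, and 0.63 with an estimated correlation), with Junb at -1.07. Adjusted over the list alone 1 of 17 fell. This fall was largest in brain, at -0.60 against -0.13 in heart and -0.17 in liver.

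The trend over log2 hours among the 21 treated arrays found 0 genes by limma (lowest adjusted p = 0.999), with 173 at an unadjusted p under 0.05. Genes of fatty acid oxidation had a mean slope of -0.06 per doubling of hours (adjusted p = 7.22e-05, and 0.484 with an estimated correlation) and hepatocyte genes -0.10 (adjusted p = 1.48e-04, and 0.546 with an estimated correlation). Heart carried the hepatocyte slope, at -0.25 against 0.03 in brain and -0.09 in liver, and without heart it was -0.03. Exocrine pancreas genes had a mean slope of -0.14 (adjusted p = 6.96e-06, and 0.484 with an estimated correlation); these were the genes high on the 1 hour liver array. The slope differed between tissues in 0 genes (F test, 100 at an unadjusted p under 0.05). Without the 1 hour arrays it differed in 1598 genes, in 1441 of which liver fell steepest, with median slopes of -0.29 in liver, 0.02 in brain and 0.03 in heart. The 95th percentile of the liver arrays was 5.31, 5.15 and 5.36 at 6, 12 and 24 hours, and 4.13, 4.52 and 4.21 at 3, 5 and 10 days. Such a difference in scale gives falling slopes for bright liver genes, and this count was made on the deposited values only. Without the 12 hour arrays 1 gene differed.

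The 6 and 12 hour arrays against those of whole days were compared because whole days fall at 1 clock time if the dose was given at 1 clock time. The labels give no clock times. In liver, Dbp-phase minus Bmal1-phase genes stood at 1.67, 1.37, 1.86 and -0.86 at 24 hours, 3, 5 and 10 days. At 6 and 12 hours they stood at 1.03 and 1.10. These genes did not stand alike on the whole days. The 10 day array lies in another array set than those of 24 hours, 3 days and 5 days. Clock state and array set cannot be told apart here, so the comparison does not separate clock times. In liver, Coq10b, a gene of coenzyme Q handling, was higher by 2.81 (SE 0.62, adjusted p = 0.0328) and Creld2, an endoplasmic reticulum stress gene, by 2.34 (SE 0.44, adjusted p = 0.016). Ugt1a6a, a glucuronosyltransferase gene, was higher by 2.33 (SE 0.39), Acaa2, a thiolase of fatty acid oxidation, by 2.08 (SE 0.31), and Gys2, liver glycogen synthase, by 2.04 (SE 0.49). Gstm4, a glutathione transferase gene, fell by 1.55 (SE 0.32), and Hsd3b2 fell by 1.43 (SE 0.26). The polymeric immunoglobulin receptor gene Pigr fell by 1.00 (SE 0.19). In all 154 genes were higher and 19 lower (limma, 2 arrays against 4), 75 and 27 with quantile normalization within tissues, and 124 and 126 with quantile normalization over all 24 arrays. The median over all genes was 0.09 here and -0.02 with that normalization; relative to the median gene Coq10b changed by 2.71 and Gstm4 by -1.65. Without brain 25 genes passed, without heart 9, and within the set of 6, 12 and 24 hours and 5 days 6; all 20 genes named by rule, Coq10b (1.91, adjusted p = 0.299) and Gstm4 (-0.89, adjusted p = 0.110) among them, kept their direction and lost their calls in that fit, which was chosen after seeing the data and has 2 arrays against 2. The call of Gys2 ended with quantile normalization within tissues (adjusted p = 0.064).

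Cell cycle genes were higher in liver at 6 and 12 hours, with a mean of 0.68 over 19 members (adjusted p = 2.94e-07, and 0.914 with an estimated correlation). Over all genes tested 8 rose, and 10 adjusted over the list alone. Mcm5 and Mcm4, subunits of the replicative helicase, rose by 1.64 (SE 0.18) and 1.52 (SE 0.24), Cdc20, which activates mitotic exit, by 1.16 (SE 0.22) and the thymidylate synthase gene Tyms by 1.15 (SE 0.19). Genes of the unfolded protein response averaged 0.87 over 15 members (adjusted p = 0.0101, and 0.914 with an estimated correlation), with 1 higher over all genes and 9 adjusted over the list alone. Male-biased liver genes averaged 1.39 over 7 members (adjusted p = 0.0352, and 0.914 with an estimated correlation), with Serpina1e at 3.78; 5 of 7 rose adjusted over the list alone. Both calls ended with quantile normalization over all 24 arrays (adjusted p = 0.0501 for each list). Ribosomal protein genes averaged 0.77 (adjusted p = 0.0177, and 0.914 with an estimated correlation; 8 of 19 higher adjusted over the list alone), but -0.17 with quantile normalization within tissues. Across the 3 tissues 0 genes passed, with 915 at an unadjusted p under 0.05, and cell cycle genes averaged 0.32 (adjusted p = 5.93e-11, and 0.62 with an estimated correlation; 9 of 19 higher adjusted over the list alone). In brain and in heart 0 genes passed, with 433 and 374 at an unadjusted p under 0.05. Ribosomal protein genes in brain averaged -0.53 (adjusted p = 1.83e-05, and 0.995 with an estimated correlation), with 0 of 19 members passing adjusted over the list alone. The 12 hour brain array carried this, with a median change from untreated of -1.44 against -0.41 at 6 hours; without it the mean against whole days was -0.06. The difference between tissues passed for 0 genes (lowest adjusted p = 0.108, 1149 at an unadjusted p under 0.05), and for 5 with a variance trend and robust eBayes.

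Single arrays gave sizes without a test. Where 1 of the 2 arrays lay below its median, as for Pcp2 on the untreated brain array (-0.01), Ccl21a at the 4 times given, Serpina1b in heart at 3 and 5 days and Acta1 on the untreated liver array (-0.53), the size is not exact. The 7 times of a tissue share 1 untreated array: in simulated unchanged arrays of the brain, heart and liver sets of genes, 12.4%, 12.7% and 12.5% of genes were lower at all 7 times and 12.5%, 12.3% and 12.8% higher. The observed shares were 20.5%, 27.7% and 11.8% lower and 8.24%, 10.4% and 4.46% higher, so 1 direction at all 7 times is common. With another array of the tissue as the reference the share went up to 22.9% lower in brain and 25.1% in liver, above the observed shares, but not above that of heart, and up to 32.5%, 18.1% and 22.0% higher in brain, heart and liver. In brain, Pcp2 was above its untreated level by 4.72 at 6 hours, 3.59 at 12 hours, 5.24 at 24 hours, 2.87 at 3 days, 5.33 at 5 days and 2.92 at 10 days. The chemokine gene Ccl21a was at -3.30, -3.71, -3.30 and -3.47 at 6, 12 and 24 hours and 5 days. The pituitary hormone genes Prl and Gh were at 2.75 and 2.54 at 1 hour, 2.67 and 2.51 at 12 hours, and 2.33 and 2.10 at 3 days, and Prl was at -1.51 at 10 days. The muscle gene Myl2 was below its untreated level at all 7 times, by a mean of -2.18 ± 1.04 (SD over 7 times), and cardiomyocyte genes averaged 1.03 on the untreated brain array, 0.98 on that of 10 days and 0.23 to 0.64 on the other 6. At least 2-fold changes numbered 10, 250, 1380, 423, 97, 443 and 18 genes from 1 hour to 10 days.

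In heart, the liver plasma protein genes Apoa2 and Serpina1b were at -5.25 and -5.22 at 5 days and at -5.17 and -5.29 at 3 days. Hepatocyte genes averaged 2.35 on the untreated heart array, 2.76 at 1 hour and 0.28 to 1.64 on the other 6. Hbb-bt was higher at all 7 times, by a mean of 1.58 ± 0.60 (SD over 7 times), as were Dbp by 1.83 ± 0.88 and Per2 by 1.72 ± 1.04. At least 2-fold changes numbered 73, 655, 629, 675, 291, 543 and 80 genes. As deposited 157 were higher and 498 lower at 6 hours and 118 and 557 at 24 hours, but 256 and 119, and 221 and 149, with quantile normalization over all 24 arrays.

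In liver, Thrsp, a regulator of lipid synthesis, was above its untreated level by 5.36 at 24 hours and 5.09 at 12 hours, and the deubiquitinase gene Usp2 by 5.37 at 24 hours and 4.65 at 5 days. Lcn2, an acute phase and glucocorticoid-responsive gene, was at 4.22 at 6 hours and 4.65 at 12 hours. Cxcl1 was lower at all 7 times, by a mean of -2.57 ± 0.66 (SD over 7 times), and Egr1, an immediate early gene, by -1.49 ± 1.05. Socs2, a growth hormone feedback gene, was at -3.76 at 5 days and -2.52 at 3 days. At 1 hour, Acta1 and Cela2a were at 5.71 and 5.62. At least 2-fold changes numbered 99, 1460, 1056, 1427, 152, 309 and 37 genes. At 6 hours 1340 of these were higher and 120 lower as deposited, and 251 and 327 with quantile normalization over all 24 arrays, for heart and liver alike an alternative chosen after seeing the data.

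**Figure D4:**
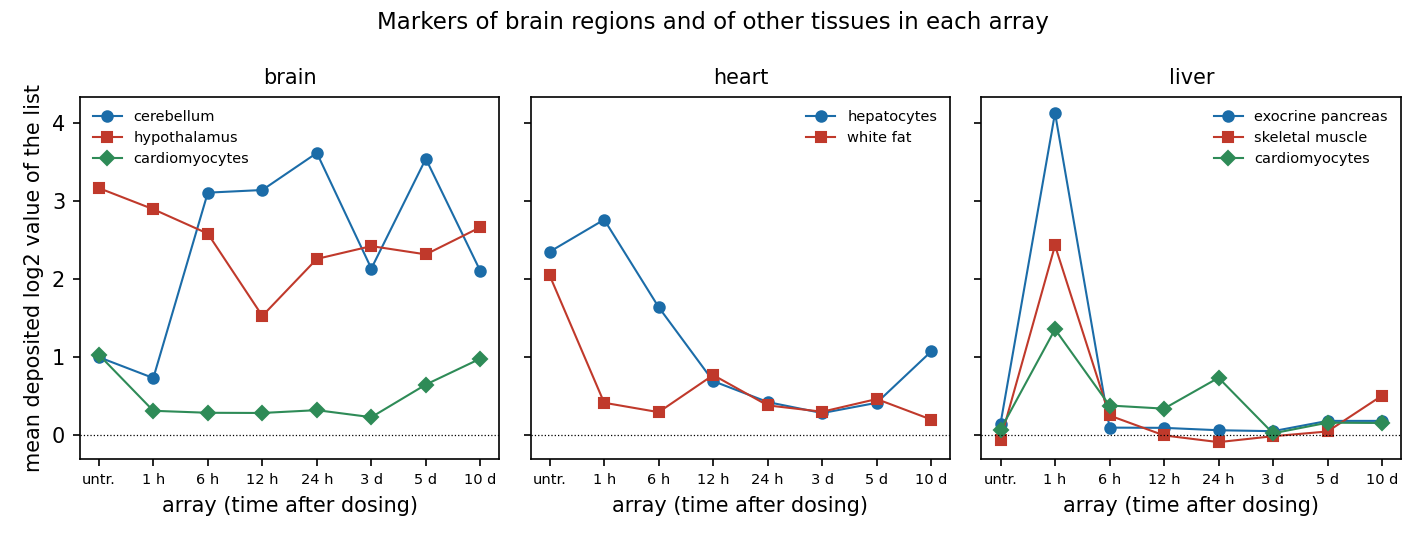
Mean log2 level (array median near 0) of genes that mark other tissues or brain regions, by array, with 1 point per array. Exocrine pancreas genes reached 4.13 on the 1 hour liver array, white fat genes (8 on the array) 2.04 on the untreated heart array, and cerebellar genes 3.61 on the 24 hour brain array against 1.00 on the untreated brain array.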

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

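All tests in this part were chosen after the results had been seen, or rerun on the deposited values after a first run on quantile-normalized values. A test of the difference between tissues picked out 3 genes whose change with treatment differed, all lower in heart; the number was 8 without the detection filter, 1 with detection on all 8 arrays of a tissue and 5 with a variance trend and robust eBayes. Adipoq changed by -3.35 in heart, 0.04 in brain and 0.13 in liver, Cidec by -2.98, 0.22 and 0.14, and Adig by -2.33, -0.02 and 0.17. This rests on 1 untreated heart array.

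The 3 genes belong to a wider fall of fat cell genes in treated heart. Fat tissue in the untreated heart sample is a candidate explanation. That 5 of the 5 tested white fat genes were highest on that array restates the fall and supports neither explanation, with Car3 at 5.53, Adipoq at 4.28, Pparg at 3.01, Cidec at 2.92 and Lep at 0.50. An effect of the treatment itself stays open: the list was at -2.42 after 1 hour and at -2.74 after 10 days, with a slope of -0.03 per doubling of hours. With 1 untreated heart array, the treatment and the content of that sample cannot be told apart.

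Calls against untreated came at 6, 12 and 24 hours, 3 days and 5 days, while 1 hour and 10 days gave 0. The tests at 1 hour and 10 days were conservative, so the 0 does not show that nothing changed then. The clock time at which tissue was taken is a candidate explanation: in the mean over 3 tissues, the Dbp-phase genes minus the Bmal1-phase genes stood at least 0.99 higher at each of the 5 times (1.12, 1.11, 1.48, 1.11 and 1.46, SD over tissues 0.70 to 0.93) than at 1 hour (0.12) and 10 days (-0.07). This partly restates the calls of the Dbp-phase list at these times and supports nothing by itself. Brain was at 0.28 at 12 hours and 0.29 at 10 days. Dosing at 1 clock time would put 10 days with 24 hours, 3 days and 5 days, and 6 and 12 hours apart from them. The means over tissues show neither, and the clock times are unknown, so the explanation stays open. Probe or labelling differences between arrays could not be excluded: at 12 hours the other probes of the called genes moved 0.648 times as far, relative to the called probe, as those of genes called between heart and brain (95% bootstrap interval 0.486 to 0.787), and 129 of 152 genes against 1267 of 1373 kept their direction. With the array set as a block, treated against untreated gave 0 calls (109 at an unadjusted p under 0.05), but that fit rests on 1 hour and 10 days, since the untreated arrays lie in 1 set, so the treatment and the array set cannot be told apart for these genes.

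In brain, cerebellar genes were higher than untreated from 6 hours on. Different brain regions in the samples are a candidate explanation. The cerebellum list exceeded the mean change of the striatum, hypothalamus and thalamus lists by 1.51 to 3.49 at 6 of the 7 times. This partly restates the rise of the cerebellum list and the fall of the hypothalamus list on these arrays, and supports nothing by itself. At 1 hour the difference was -0.28, which that explanation leaves open, since the untreated and 1 hour samples could hold alike shares of cerebellum. No biological explanation was tested for this pattern, and the single untreated brain array leaves the treatment open.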

How the results depend on the processing

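The array sets and quantile normalization over all 24 arrays were chosen after seeing the data; the others beforehand. Leaving out a tissue (brain, heart, liver) changed the number of genes against untreated from 364 to 3, 0 and 1487 at 6 hours, from 587 to 1, 0 and 2710 at 12 hours, from 295 to 6, 0 and 1635 at 24 hours, from 35 to 1, 0 and 172 at 3 days, from 216 to 2, 0 and 1374 at 5 days, and from 471 to 2, 0 and 1866 for any time. Without brain or heart the liver difference between 6 and 12 hours and whole days went from 173 to 25 and 9, and the treatment difference between tissues from 3 to 0 without heart. With the values as deposited, the slope difference between tissues went from 0 to 1598 without 1 hour and to 1 without 12 hours. Quantile normalization within tissues gave 902 genes for any time, 57 at 3 days and 102 for liver at 6 and 12 hours; over all 24 arrays it gave 842 for any time and 53 at 3 days. A variance trend with robust eBayes gave 64 at 3 days, 1 for treated liver, and 5 for both differences between tissues (treatment; 6 and 12 hours against whole days). Without the detection filter the tissue contrasts gave 11914, 13176 and 11173 and the treatment difference 8; detection on all 8 arrays gave 1 for that difference and 7 in place of 12 in heart. Within the set of 6, 12 and 24 hours and 5 days, 6 genes passed in liver at 6 and 12 hours. Single-array changes totalled 2621 in brain, 2946 in heart and 4540 in liver; at 1.5-fold they totalled 9929, 11717 and 11929, and against the mean of the other 7 arrays 755 in brain and 416 in heart. Quantile normalization gave 1856 in heart and 2035 in liver within tissues, and 1889 and 2266 over all 24 arrays. Lists reversed with quantile normalization within tissues and over all 24 arrays: xenobiotic metabolism at 24 hours (from 0.304 to -0.0222 and -0.0349) and ribosomal proteins in liver at 6 and 12 hours (from 0.77 to -0.17 and -0.15). Except where fewer arrays or another gene set were used by construction, the cause was not tested. Named genes gave 940 comparisons with direction and call unchanged, 337 in which the call ended and 0 reversed; lists gave 463, 130 and 4. Of the counts for single arrays 134 stayed within 1.5 times and 55 did not. Fits without background correction were not run, since they need the table whose columns match no label, and signal over background is unknown. No paired analysis was possible by animal, because the labels do not say which tissues came from the same animals; time and tissue served as blocks.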

Other observations

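The split tests below were rerun on the deposited values after a first run had been seen; the single-array values have no test. In brain, genes of microglia and macrophages had a median change of -0.84, -1.15, -0.80 and -0.70 at 6, 12 and 24 hours and 5 days, at or below percentile 0.03 of random lists of the same size and expression, against -0.16 at 1 hour, -0.33 at 3 days and -0.21 at 10 days. Genes of MHC class II antigen presentation in brain were at -0.72, -0.87, -0.76 and -0.86 at the same 4 times, and at -0.38 at 3 days and -0.36 at 10 days. On the arrays of those 4 times cerebellar genes were at 2.16, 2.38, 2.80 and 2.71 and hypothalamic genes at -0.86, -1.74, -1.12 and -1.05. In liver, genes of cholesterol synthesis had a median change of 1.07, 1.14 and 1.34 at 6, 12 and 24 hours, and 0.27, 0.42 and 0.39 with quantile normalization over all 24 arrays. Glucocorticoid-responsive genes in liver were at 1.39, 1.80 and 1.82 at 6, 12 and 24 hours, and 0.67, 0.94 and 0.82 with that normalization. Hepatocyte genes in liver were at 2.14 and 2.00 at 6 and 12 hours as deposited and at -0.10 and -0.06 quantile-normalized.

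In heart, interferon-stimulated genes averaged 0.20 over 20 members at 6 and 12 hours against whole days (adjusted p = 3.26e-04, and 0.866 with an estimated correlation; 0 of 20 passing adjusted over the list alone). The 6 hour array carried this, at 0.37 against 0.03 for the 12 hour array. Cell cycle genes there averaged 0.23 (adjusted p = 8.42e-08, and 0.866 with an estimated correlation), with 5 of 19 higher adjusted over the list alone, among them Birc5 at 0.66 and Top2a at 0.63. Each array was also compared with the other 7 of its tissue by limma. The fit used 1 spread pooled over the 3 tissues and assumed the lone array to vary like the rest. The 12 hour brain array differed in the most genes, followed by the 1 hour liver, 5 day liver and untreated heart arrays. Some treated arrays thus stood apart in this way more than the untreated heart array did.

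Other splits of the samples were counted. The 471 genes for any time were reached by 1 of 100 permutations of the times within tissues, the real one, and the highest other gave 0, so chance can be excluded for permutations of this kind. They break up the array sets that the 3 tissues of a time share, so the 471 genes may come from the array set alone. The 0 genes of treated against untreated were reached by 100 of 100 splits, the highest other giving 36; the 0 genes of the trend by 100 of 100, the highest other 204; and the 0 genes of 6 and 12 hours against whole days across tissues by 100 of 100, the highest other 51. A count of 0 is reached by every split, so these splits say nothing about chance. Why some other splits gave up to 36, 204 and 51 calls was not tested. The tissue contrasts, fitted without the time block, gave 8169 genes for heart against brain (highest other 0), 8042 for liver against brain (highest other 6400) and 7087 for liver against heart (highest other 5276), each reached by 1 of 100 splits, so chance can be excluded. Single times against untreated have only 4 splits, too few for a share under 0.05. The real values of 364, 587, 295, 35 and 216 at 6, 12 and 24 hours, 3 days and 5 days were each reached by 1 of 4, with 0 as the highest other, and the 0 genes at 1 hour and at 10 days by 4 of 4, with 0 as the highest other.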
